A study of Mus musculus with 8 samples.

How the data were processed

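Liver RNA of 8 mice was measured by sequencing of polyadenylated RNA, with a stranded TruSeq mRNA library kit, per the labels' protocols. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.1, Picard 1.84, RSEM 1.2.22 and DESeq2 and the genome build mm10. The deposited tables give RSEM expected counts per gene, which are estimated counts that divide reads shared by several genes and need not be whole, and the authors' TPM values, which are scaled to gene length and to the same total in each liver. The strand setting of the counting and the annotation release are not given in the sources used here. All 55450 gene identifiers, with versions and symbols, matched GENCODE M21, which supplied coordinates on mm10.

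Samples were grouped by the genotype in their titles, 4 controls (floxed Cebpa, no Cre) and 4 knockouts (Cre), with the replicate numbers of the titles. Nothing in the labels ties a number to a litter or a day, and the deviations of same-numbered livers from their group means correlated at 0.207, 0.009, -0.024 and -0.067, so the numbers were not used as pairs. No pair of livers in a group agreed within sampling noise, so n = 4 per group. The labels give no batch.

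The expected counts were rounded to whole numbers and fitted in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr by group, with a minimum count of 10 and a minimum total of 15, which left 13303 of the 23236 genes with any count. TMM factors scaled the libraries, and the robust quasi-likelihood test compared knockout with control, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The SE of a log2 fold change was computed from the fold change and the test's F statistic. Levels are CPM on TMM-scaled library sizes, and log2 CPM used a prior count of 2. Exact permutation tests of Cebpa, Orm1 and Orm2 used all 70 splits of the livers. A count of 1 was worth 0.0341 to 0.0485 CPM, and counting intervals at 95% are exact binomial intervals that cover counting error only.

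The 39 gene lists were written before the data were examined. Lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01 and adjusted over the 36 lists. Numbers of list members called by DESeq2 are over the members that edgeR tested, of which DESeq2 gave no adjusted p for 2 stellate cell genes and 5 acute phase genes. Genes were named by a rule fixed at the same time: Cebpa and the Orm genes, the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM and no overlap between groups (predicted, clone and pseudogene names left out), the 4 members of each list with the smallest adjusted p with the best 2 of the opposite direction, and the 10 most abundant genes. The text names 82 tested genes of which 71 came from the rule and 11 were chosen after their values were seen.

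The steps were tested on simulated data, with 200 genes changed by known folds in libraries drawn from the real means and sizes. Other settings fixed before the data were examined were RLE factors, library size alone, no filter, a filter of 1 CPM in 4 livers, DESeq2 1.42.0, limma-voom on unrounded counts, limma-trend on log2(TPM + 1), a fit without robust estimation, a block for the replicate number, each liver left out in turn, glmTreat against a fold change of 1.5, camera with an estimated correlation, fry, and list members held by 1 list only. Removal of control 2 and knockout 4 together was added after seeing the data. The table of the whole series held the same values as the per-liver tables and was not fitted separately. Figures were drawn with matplotlib 3.10.9.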

Results

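RNA was measured in 8 mouse livers, 4 from mice with floxed Cebpa and no Cre (controls) and 4 from mice whose hepatocytes lacked Cebpa (knockouts). Cebpa encodes C/EBP alpha, a transcription factor of differentiated hepatocytes. The mice were 10 weeks old, took a liquid control diet for 5 days and then a liquid diet with 5% ethanol by volume for 4 weeks. The comparison asks which liver genes differ between the genotypes under ethanol feeding, with attention to Orm1, which the series names together with Cebpa. Livers without ethanol are not analysed here, so no value below measures a response to ethanol. The expected counts summed to between 21048350 (control 2) and 28148744 (knockout 4) per liver. At that depth 1 count was worth 0.0341 to 0.0485 CPM. All 8 livers expressed the Y-linked gene Ddx3y, at 55.1 to 75.1 CPM.

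Cebpa was 41.5-fold lower in the knockout livers. The gene (ENSMUSG00000034957.10) lies on chromosome 7 of mm10, from 35119293 to 35121928 on the plus strand. Its level was 319.9, 263.6, 269.3 and 320.3 CPM in controls 1 to 4 and 5.44, 9.26, 7.31 and 6.24 CPM in knockouts 1 to 4. The log2 fold change was -5.38 (SE 0.18, edgeR adjusted p = 4.78e-07), so the values followed the genotype labels in all 8 livers. A two-sided exact permutation test gave p = 0.0286, the smallest that 70 splits of 4 against 4 allow. Reads of the antisense gene Gm45091, which overlaps Cebpa, cannot be separated from it if the counting ignored strand, a setting not given in the sources used here.

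Orm1, which encodes the acute phase plasma protein orosomucoid, was lower in every knockout liver than in any control. Its level was 275.0, 1413, 143.7 and 61.2 CPM in controls 1 to 4 and 0.359, 0.475, 0.183 and 2.76 CPM in knockouts 1 to 4. The log2 fold change was -8.87 (SE 1.56, edgeR adjusted p = 0.0464), with an exact permutation p = 0.0286, again the smallest possible. Orm1 (ENSMUSG00000039196.2) lies on chromosome 4 from 63344560 to 63348163, close to its paralog Orm2, at 63362449 to 63365878. Orm2 was at 12.7, 340.6, 7.04 and 2.0 CPM in controls and 0.943, 1.07, 1.60 and 1.81 CPM in knockouts, a difference that did not pass the test (log2 fold change -6.04, SE 1.92, edgeR adjusted p = 0.172). Control 2 carried most of that difference, and without it the log2 fold change of Orm2 was -2.41 (adjusted p = 0.103). Orm3 had too few counts to be tested, with 109 counts over the 4 controls and 1 over the 4 knockouts, a ratio of 120 with a 95% counting interval of 21.1 to 4790. Reads shared by the Orm paralogs were divided by the authors' estimation, so the level of each one is uncertain. Their sum does not depend on that division. The 3 genes summed to 564.8 ± 799 CPM in controls and 2.31 ± 1.52 CPM in knockouts (SD, n = 4, exact permutation p = 0.0286). The Orm1 call was close to the threshold. Control 2 carried much of the control mean, and without it the log2 fold change was -7.29 (adjusted p = 0.0259), while without knockout 4 it was -10.40 (adjusted p = 0.0547). The call was lost in 6 of the 8 leave-one-out fits, all but those without control 2 or control 4, with adjusted p up to 0.146 without knockout 2.

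**Figure D1:**
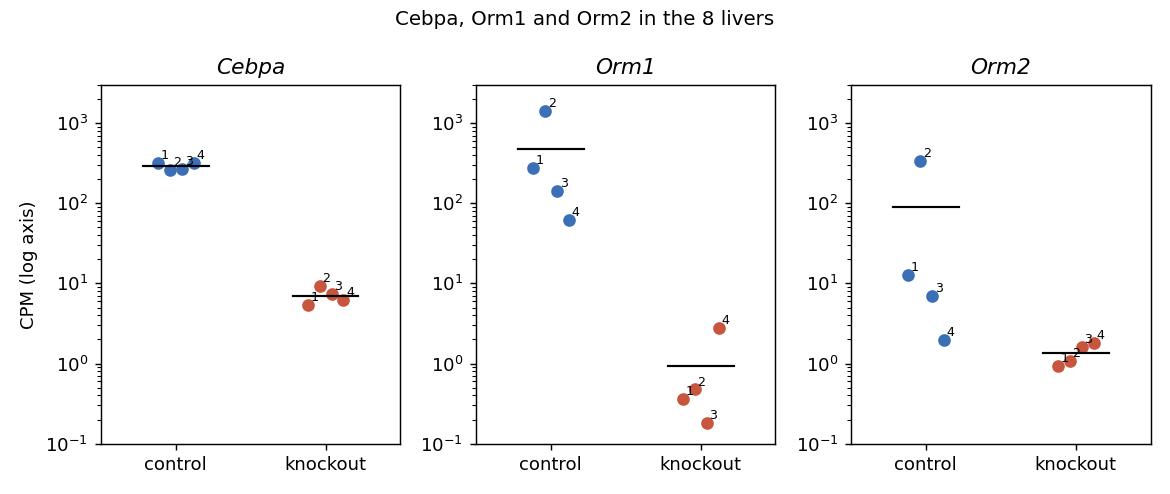
Level of Cebpa, Orm1 and Orm2 in CPM on a log axis, with 1 point per liver, numbered by replicate, and a horizontal line at the mean of each group of 4. Control 2 has the highest Orm1 (1413 CPM) and Orm2 (340.6 CPM), and the knockout livers lie below all controls in each panel.

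Over the whole transcriptome, 13303 genes had enough counts to be tested, and 274 differed between the genotypes at an edgeR adjusted p below 0.05. Of these, 113 were higher and 161 lower in the knockouts, and 79 and 70 of them changed at least 2-fold. With library sizes alone as scaling the split was 161 higher and 115 lower, and on log2(TPM + 1) values it was 101 and 70. All 274 genes had no overlap between the groups, as had 1525 of all tested genes, or 11.5%, where chance gives 2.86%. A total of 2462 of the 13303 tested genes had an unadjusted p below 0.05. The counts of list members at that level, given below, are to be read against this share. In a simulation with the sizes, mean levels and gene-wise spread of the 8 libraries, the test recovered 28.8% of genes changed 1.5-fold, 75.8% of genes changed 2-fold and 95.3% of genes changed 4-fold, and 8.45% of its calls were false. Its genes were drawn independently, with no liver set apart as control 2 and knockout 4 were, so the real rates may differ. Leaving out control 2 and knockout 4, the livers farthest from their groups, gave 185 higher and 246 lower genes, an alternative chosen after seeing the data. Leaving out 1 liver at a time gave between 108 called genes, without knockout 2, and 372, without knockout 4.

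The largest rises were in genes nearly silent in control livers. Spink1, a trypsin inhibitor of the pancreas, had 3 counts over the 4 controls and 349 over the 4 knockouts, a ratio of 105 (95% counting interval 35.8 to 514). Lrtm2 rose 43.1-fold, from 0.142 to 6.48 CPM, with a log2 fold change of 5.43 (5.24 to 6.06 with 1 liver left out). H19, an imprinted noncoding RNA of fetal tissues, rose 26.0-fold, with a log2 fold change of 4.70 (4.40 to 5.38 with 1 liver left out). The actin-bundling gene Pls1 rose 24.9-fold, from 0.516 ± 0.311 to 13.1 ± 7.39 CPM (SD, n = 4). Corin, Bex4, Gipc2, Sdcbp2 and Smpdl3b rose between 9.22-fold and 18.6-fold. The log2 fold changes of Corin, Bex4 and Sdcbp2 were 4.22, 4.14 and 3.86 with all livers. With 1 liver left out they ran from 3.85 to 4.87, 3.86 to 4.80 and 3.37 to 4.61. Cyp2c55, a cytochrome P450, rose 8.08-fold, from 1.65 ± 0.471 to 13.4 ± 5.55 CPM (SD, n = 4). The edgeR adjusted p of these genes ran from 0.000274 for Lrtm2 to 0.017 for H19 and Corin. H19 and Corin lost the call in 4 and 3 of the 8 fits that left out 1 liver, with adjusted p up to 0.0598 and 0.0552, both without control 1. H19, Corin, Gipc2 and Cyp2c55 overlap genes on the opposite strand, and H19 also holds Mir675 on its own strand.

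Among the largest falls were abundant secreted proteins of the hepatocyte. Mup7 and Mup3, which encode major urinary proteins, fell 128.9-fold and 17.2-fold, Mup3 from 4788 ± 751 to 278.0 ± 144 CPM (SD, n = 4). Serpina1e, of the alpha-1 antitrypsin family, fell 101.5-fold, from 3074 ± 1923 to 30.2 ± 34.9 CPM (SD, n = 4). Cldn14, a tight junction claudin, had 271 counts over the controls and 3 over the knockouts, a ratio of 99.6 (95% counting interval 33.7 to 486). Nnmt, nicotinamide N-methyltransferase, fell 45.2-fold, and Tiam2, the complement regulator Susd4 and the complement gene C4a fell between 13.6-fold and 30.5-fold. Apart from Cebpa, their edgeR adjusted p ran from 0.000328 for Cldn14 to 0.0464 for Orm1. The log2 fold change of Serpina1e, -6.67 with all livers, ran from -7.80 without knockout 4 to -6.12 without control 2. Serpina1e, Nnmt and C4a lost the call in 7, 7 and 6 of the 8 leave-one-out fits, with adjusted p up to 0.136 without knockout 2 for Serpina1e, and 0.0847 and 0.0831 without knockout 1 for Nnmt and C4a. The Mup, Serpina1 and C4 genes share reads with near-identical copies, so the level of each one is uncertain, and Tiam2 overlaps Tfb1m on the opposite strand.

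Gene lists were fixed before the data were examined, and 36 of the 39 had the 5 tested members a list test required. By camera with a preset correlation, 16 passed an adjusted p of 0.05. None passed with an estimated correlation, where the lowest adjusted p = 0.189. That was the fetal liver list, whose estimated correlation of 0.00296 lay below the preset 0.01, yet whose camera adjusted p had been 0.000186. The versions of the test therefore differ in more than the correlation used. A list that passes only with the preset value is not shown to owe its call to correlated genes. Other splits of the 8 livers into 4 and 4 often gave as many lists, 22 at the highest, so the list tests are given below as descriptions beside the member counts. Splits that keep most livers of a genotype together retain part of the genotype contrast, so this comparison is not a clean measure of chance.

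Of the 22 acute phase genes tested, all had a negative log2 fold change, with a median of -1.19, but edgeR called Orm1 alone (camera adjusted p = 4.15e-06, and adjusted p = 0.529 with an estimated correlation). An unadjusted p below 0.05 was found for 15, and DESeq2 called 2 lower and gave no adjusted p for 5. Lcn2 was at 54.5 ± 90.5 CPM in controls and 1.96 ± 0.820 CPM in knockouts (SD, n = 4, edgeR adjusted p = 0.158). The haptoglobin gene Hp was at 3798 ± 2864 and 1489 ± 276 CPM (SD, n = 4, adjusted p = 0.158), and Lbp at 80.0 ± 44.2 and 33.5 ± 6.57 CPM (SD, n = 4, adjusted p = 0.114). The mean log2 CPM of the list was 9.82 in control 2, and 7.19 to 7.86 in the other controls against 6.36 to 6.91 in the knockouts. Without control 2 the median was -0.575, the log2 fold change of Lcn2 was -2.23 (-4.77 with all livers) and that of Hp -0.67 (-1.35), and Orm1 and Lbp were called (Lbp log2 fold change -0.79, adjusted p = 0.032). Without knockout 4 no gene of the list was called.

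**Figure D2:**
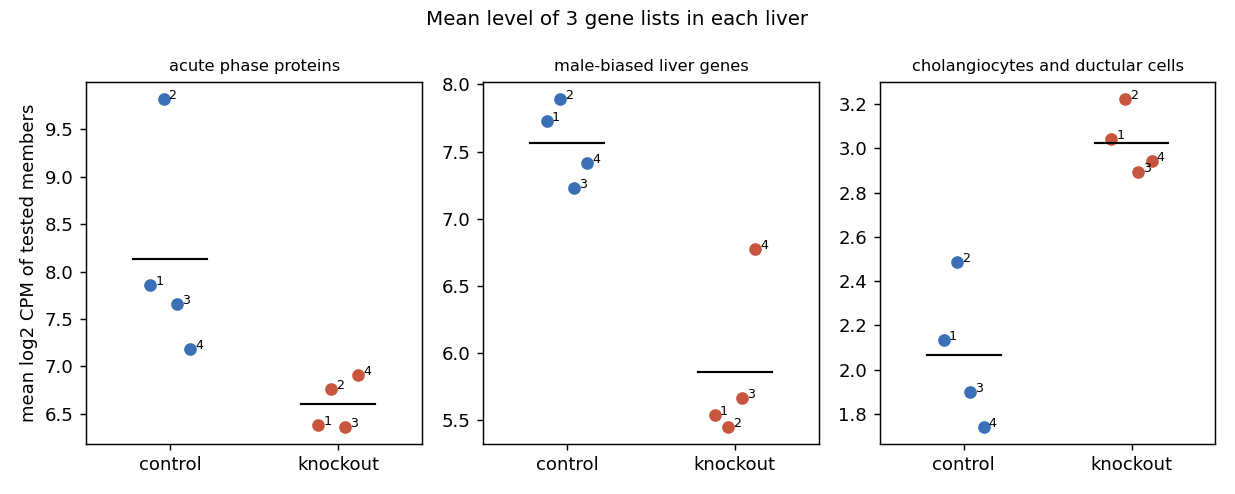
Mean log2 CPM of the tested members of the acute phase, male-biased and cholangiocyte lists, with 1 point per liver, numbered by replicate, and a horizontal line at the group mean. Control 2 stands apart for acute phase genes at 9.82, and knockout 4 for male-biased genes at 6.77.

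Other plasma protein genes of the hepatocyte were lower in part. Among 27 genes of secreted proteins and apolipoproteins, 6 fell and none rose, 6 also when adjusted over the list alone (camera adjusted p = 8.85e-06, and adjusted p = 0.297 with an estimated correlation). Besides Igfals and Serpina6, the genes called were all of the Serpina1 family, whose near-identical copies share reads. The 6 calls are therefore not independent. Serpina1a fell 2.82-fold (edgeR adjusted p = 0.00364), Serpina1c 2.74-fold, Serpina1d 2.05-fold, and Igfals, which carries IGF1 in plasma, 1.55-fold. Alb was at 78419 ± 13539 CPM in controls and 89436 ± 4591 CPM in knockouts (SD, n = 4, adjusted p = 0.532). Of 20 coagulation genes, 3 fell (6 adjusted over the list alone): F11 2.61-fold, Cpb2 2.08-fold and F5 1.46-fold (camera adjusted p = 3.1e-05, and adjusted p = 0.529 with an estimated correlation). Of 20 complement genes, none passed edgeR's test (2 lower adjusted over the list alone), 7 had an unadjusted p below 0.05 and DESeq2 called 5 (camera adjusted p = 0.000312, and adjusted p = 0.529 with an estimated correlation). C4bp and Serping1 had edgeR adjusted p of 0.0685 and 0.0836. The call of Cpb2 was lost in 6 of the 8 leave-one-out fits, with adjusted p up to 0.119 without knockout 2. F5 lost it in 2, with adjusted p up to 0.0655 without knockout 2.

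Of 19 male-biased liver genes tested, 5 fell and none rose, 9 adjusted over the list alone. Of the 19, 15 had a negative and 4 a positive log2 fold change, with a median log2 fold change of -1.21 (camera adjusted p = 1.1e-06, and adjusted p = 0.474 with an estimated correlation). The 5 that fell were Mup7, Serpina1e, Mup21 (3.94-fold lower, edgeR adjusted p = 0.017), Cyp2u1 (2.43-fold lower, adjusted p = 0.0177) and Mup12 (4.41-fold lower, adjusted p = 0.0464). Serpina1e (101.5-fold lower, adjusted p = 0.0405) was called in 1 of the 8 leave-one-out fits. Mup12 was outside the naming rule and was chosen after its values were seen. It lost its call in all 8 leave-one-out fits, with adjusted p up to 0.12 without knockout 1, and Mup21 and Cyp2u1 lost theirs in 2 and 3, with adjusted p up to 0.0581 and 0.0615 without knockout 2. The mean log2 CPM of the list was 6.77 in knockout 4, 5.45 to 5.66 in the other knockouts and 7.23 to 7.89 in the controls. Of 15 female-biased genes tested, Ntrk2 rose 5.56-fold and Cyp2c40 and Cyp2c69 fell 4.22-fold and 7.28-fold (camera adjusted p = 0.936, direction up, with a median of -0.144). Adjusted over the list alone 2 were higher and 3 lower. The 3 calls were lost in 6, 3 and 6 of the 8 leave-one-out fits, with adjusted p up to 0.108 without control 1, 0.0721 without knockout 1 and 0.117 without knockout 2.

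Genes of ducts and of progenitors were higher in part. Of 16 cholangiocyte and ductular genes, 5 rose and none fell, 14 adjusted over the list alone, with a median log2 fold change of 1.02 (camera adjusted p = 6.94e-09, and adjusted p = 0.297 with an estimated correlation). Spp1, osteopontin, rose 6.02-fold, from 35.1 ± 16.8 to 211 ± 103 CPM (SD, n = 4), the epithelial adhesion gene Epcam 2.80-fold, Pkhd1 2.23-fold, Bicc1 2.07-fold and the duct keratin Krt19 3.26-fold. Krt19 was chosen after its values were seen. Their edgeR adjusted p ran from 0.021 to 0.0467, and each call was lost in 4 to 7 of the 8 leave-one-out fits, with adjusted p up to 0.125 without knockout 2 for Bicc1. Of 18 genes of fetal liver and progenitors, H19, Lpl and Scd2 rose, and adjusted over the list alone 7 were higher and 1 lower (camera adjusted p = 0.000186, and adjusted p = 0.189 with an estimated correlation). Lpl, lipoprotein lipase, rose 6.18-fold, from 19.0 ± 4.37 to 117.4 ± 35.3 CPM (SD, n = 4, edgeR adjusted p = 0.00262), and Scd2 rose 1.86-fold, a call lost in 7 of 8 leave-one-out fits, with adjusted p up to 0.127 without knockout 2.

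No macrophage, stellate, endothelial or inflammatory gene passed edgeR's test. All 23 macrophage and Kupffer genes had a positive log2 fold change, with a median of 0.522, 9 at an unadjusted p below 0.05 and 1 called by DESeq2 (camera adjusted p = 9.46e-06, and adjusted p = 0.529 with an estimated correlation). Lyz2 was at 28.7 ± 9.12 CPM in controls and 50.3 ± 8.63 CPM in knockouts (SD, n = 4, edgeR adjusted p = 0.114). Of 26 stellate cell and fibrosis genes, 24 were positive, 13 had an unadjusted p below 0.05 and DESeq2 called 1 (camera adjusted p = 9.07e-06, and adjusted p = 0.529 with an estimated correlation). Col4a1 was at 28.3 ± 4.63 and 56.6 ± 21.5 CPM (SD, n = 4, adjusted p = 0.102). Of 20 inflammatory genes, 9 had an unadjusted p below 0.05, and DESeq2 called 1 higher and 1 lower. Adjusted over the list alone, 2 were higher and 1 lower (camera adjusted p = 0.00125, and adjusted p = 0.474 with an estimated correlation). Of 20 endothelial genes, 5 had an unadjusted p below 0.05, as had 2462 of all 13303 tested genes. DESeq2 called 0 of the endothelial genes, and their median was 0.218 (camera adjusted p = 0.00125, and adjusted p = 0.529 with an estimated correlation). Of 7 erythroid genes, the heme synthesis gene Alas2 fell 2.15-fold (camera adjusted p = 0.00127, and adjusted p = 0.474 with an estimated correlation), and without control 2 and knockout 4 the list had a camera adjusted p = 0.0578. Neutrophil, lymphocyte, and pancreas and adipose lists had 1, 4 and 4 tested members and were not tested as lists.

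In the oxidative stress list 4 of 26 genes rose, all glutathione transferases, 4 also when adjusted over the list alone (camera adjusted p = 0.0378, and adjusted p = 0.529 with an estimated correlation). Gstm3 rose 7.13-fold, from 38.7 ± 7.13 to 275.4 ± 101 CPM (SD, n = 4), Gsta2 6.37-fold, Gstm2 2.29-fold and Gstm1 1.89-fold. The list's call was lost without control 1, control 4 or knockout 1, at adjusted p of 0.0651, 0.159 and 0.0813. Gsta2, Gstm2 and Gstm1 lost their calls in 6, 4 and 5 of the 8 leave-one-out fits, with adjusted p up to 0.0864 without control 2, 0.0913 without knockout 2 and 0.0838 without control 4. Reads shared by members of this family make each level uncertain. In the endoplasmic reticulum stress list 2 of 22 genes fell, Creld2 2.02-fold and Atf6 1.48-fold, 9 adjusted over the list alone (camera adjusted p = 1.36e-05, and adjusted p = 0.474 with an estimated correlation), and these calls were lost in 6 and 4 of the 8 leave-one-out fits, with adjusted p up to 0.103 and 0.0905 without knockout 2. No gene was called in the circadian list (17 tested, 2 at an unadjusted p below 0.05, DESeq2 0, camera adjusted p = 0.0134, and adjusted p = 0.346 with an estimated correlation). The same held for the 44 cytosolic ribosomal protein genes (3 at an unadjusted p below 0.05, DESeq2 0, camera adjusted p = 6.76e-05, and adjusted p = 0.723 with an estimated correlation), whose median was -0.112.

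**Figure D3:**
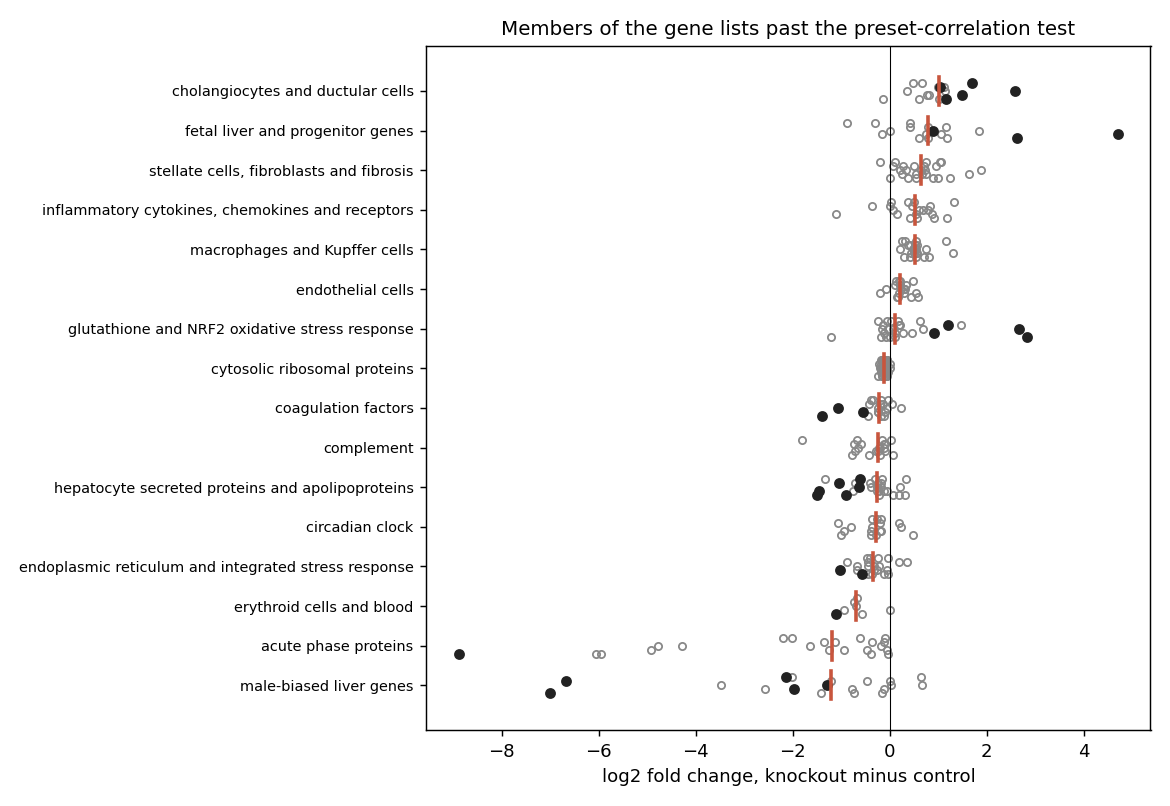
Log2 fold change (knockout minus control) of each tested member of the 16 lists past the camera test with a preset correlation. Filled points are genes with an edgeR adjusted p below 0.05, open points are other members and red bars are medians, from -1.21 for male-biased genes to 1.02 for cholangiocyte genes.

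Gys2, liver glycogen synthase, fell 1.72-fold (edgeR adjusted p = 0.0083) and was the 1 of 19 gluconeogenesis and glycogen genes called (camera adjusted p = 0.325, and 0.0472 without control 2). Slc10a1, the bile acid importer of hepatocytes, fell 1.58-fold (adjusted p = 0.0493) among 24 bile acid genes (1 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.332), a call lost in 7 of 8 leave-one-out fits, with adjusted p up to 0.122 without knockout 2. Of 25 lipid droplet and handling genes, edgeR called Lpl alone, and DESeq2 called 3 higher and 1 lower. Adjusted over the list alone 4 were higher and 1 was lower (camera adjusted p = 0.132, and 0.0374 without control 4). Plin2 was at 359 ± 55.4 and 547 ± 131 CPM (SD, n = 4, edgeR adjusted p = 0.114). Of 15 genes of ethanol and acetaldehyde metabolism, edgeR called none, 1 had an unadjusted p below 0.05 and DESeq2 called 1 (camera adjusted p = 0.587). Cyp2e1, the ethanol-oxidizing P450, was at 10713 ± 959 CPM in controls and 10677 ± 1455 CPM in knockouts (SD, n = 4, adjusted p = 0.989), with a log2 fold change that changed sign between settings. EdgeR also called none of 21 genes of fatty acid and triglyceride synthesis (2 at an unadjusted p below 0.05, DESeq2 1, camera adjusted p = 0.658), 30 of fatty acid oxidation (6 and 3, camera adjusted p = 0.658), 23 of cholesterol synthesis (0 and 0, camera adjusted p = 0.544) and 26 of the urea cycle and amino acid catabolism (9 and 6, camera adjusted p = 0.0936). The last list passed camera in 6 alternatives, with adjusted p of 0.0472 with library size alone, 0.0345 without a filter, 0.0188 and 0.0313 without control 2 and control 4, and 0.0432 and 0.00766 without knockout 1 and knockout 3. In it 8 genes were lower when adjusted over the list alone, and Cps1 and Asl had adjusted p of 0.0763 and 0.091.

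Of 31 xenobiotic P450s and receptors, edgeR called Cyp2c55 alone, and DESeq2 called 2 higher and 4 lower. Adjusted over the list alone 1 was higher and 2 were lower (camera adjusted p = 0.883). Rhbg, an ammonium transporter of pericentral hepatocytes, rose 2.05-fold and was the 1 called by edgeR of 18 pericentral genes. Adjusted over the list alone 1 was higher and 2 were lower (camera adjusted p = 0.361), and DESeq2 called 1 higher and 3 lower. Of 27 C/EBP and liver transcription factor genes, DESeq2 called 2 higher and 2 lower. EdgeR called Cebpa alone (camera adjusted p = 0.0691, and 0.0343 and 0.0454 without control 2 and knockout 3). Since the list holds Cebpa, the deleted gene, part of its fall was set by the design. Cebpb, of the same family as Cebpa, was at 118.7 ± 24.5 and 173.7 ± 33.0 CPM (SD, n = 4, edgeR adjusted p = 0.132). Gsdmd fell 1.94-fold among 17 p53 and cell death genes (camera adjusted p = 0.949), a call lost in 7 of 8 leave-one-out fits, with adjusted p up to 0.119 without knockout 2. EdgeR called none of 18 periportal genes (1 higher and 1 lower adjusted over the list alone, 5 at an unadjusted p below 0.05, DESeq2 3, camera adjusted p = 0.942), 20 iron genes (5 and 1, camera adjusted p = 0.936), 28 interferon genes (8 and 0, camera adjusted p = 0.148, and 0.0303 without knockout 3), 28 proliferation genes (2 and 2, camera adjusted p = 0.995, direction up, and 0.0462, direction down, without knockout 2) and 13 immediate early genes (3 and 2, camera adjusted p = 0.325). The same was found for 13 mitochondrially encoded messenger RNAs (0 and 0, camera adjusted p = 0.234, and 0.000661 without control 2) and 43 nuclear genes of oxidative phosphorylation (0 and 0, camera adjusted p = 0.157, and 0.0194, 0.0471 and 0.0486 without control 1, knockout 2 and knockout 4). Among the other named genes, Serpina1c, F5, Cyp2u1, Col4a1, Pkhd1, Bicc1, Alas2 and Cebpb overlap genes on the opposite strand, so their levels are uncertain if the counting ignored strand. Scd2, Rhbg and Spp1 overlap genes on their own strand, which a stranded count cannot separate either.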

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

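The tests of control 2, of knockout 4 and of cell types below were chosen after the values were seen, and the counts over other splits of the livers were planned before. Each group of 4 livers was searched for a liver far from the other 3, relative to the group's range. Of 248 groups searched, 22 had one. Chance alone would give about 1 in 20, or 12.4, if the values were independent and normally distributed. Many of these genes move together and their levels were taken in CPM, so 12.4 is only a rough guide. Control 2 was that liver in 9 cases and knockout 4 in 6.

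Control 2 stood apart from the other controls in acute phase and related genes. It held 1413 CPM of Orm1, against 61.2 to 275.0 in the others, 340.6 CPM of Orm2 (2.0 to 12.7), 190.2 CPM of Lcn2 (3.95 to 13.9), 8079 CPM of Hp (2043 to 2608) and 145.8 CPM of Lbp (50.8 to 62.2). It was also far from the others for Serpina1e at 5952 CPM, Gys2 at 388.4 CPM, Gstm1 at 1039 CPM and Cyp39a1 at 68.4 CPM. A knockout liver labelled as a control is argued against by Cebpa, at 263.6 CPM against at most 9.26 CPM in the knockouts. Immune cells as the source of the summed acute phase transcripts are argued against by abundance. The summed acute phase genes exceeded those of the highest other control by 29490 CPM. The summed macrophage and neutrophil markers exceeded theirs by 61.2 CPM, or 0.207% of that. These markers reached only 535.1 CPM in control 2, so even a large relative rise would stay far below 29490 CPM. The sum weighs abundant genes such as Hp most and does not settle the source of less abundant ones such as Lcn2. Whether the liver held more immune cells stays open, since its macrophage score lay 1.25 SD above the mean of the other controls and its neutrophil markers 3.12 SD above, on 58 counts. The design gives the controls no second condition, so no biological explanation tied to a group was tested.

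Knockout 4 lay closest to the controls in male-biased genes, with a mean log2 CPM of 6.77 against 5.45 to 5.66 in the other knockouts. It also stood apart in Mup16 at 35.2 CPM (6.65 to 7.82), Serpina1c at 3385 CPM (2084 to 2271), Lbp at 43.3 CPM (29.8 to 31.0), Orm1 at 2.76 CPM (0.183 to 0.475) and the complement list at 8.67 (8.41 to 8.44). Incomplete Cebpa deletion is argued against by its Cebpa level of 6.24 CPM, below the highest other knockout at 9.26 CPM. RNA of a control liver would have to make up 5.95% of the sample to give its Mup3 level, which predicts 24.3 CPM of Cebpa. No other explanation of knockout 4 was tested.

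Of the marker genes of other cell types, edgeR called 5 of 16 cholangiocyte genes higher. It called no macrophage, stellate or endothelial gene, though most had positive log2 fold changes. DESeq2 called 7 cholangiocyte, 1 macrophage, 1 stellate and 0 endothelial genes higher. A lower share of hepatocyte RNA alone would raise all of them alike. The mean of the cholangiocyte list differed between the genotypes by 0.719 more than that of the endothelial list on the log2 scale (exact permutation p = 0.0286, the smallest possible, and 0.114 adjusted over the 4 lists set against endothelial genes), with no overlap between the groups in this difference. The cholangiocyte list thus rose more than the endothelial list, which a lower hepatocyte share alone would not give. The adjusted p is above 0.05, however, and endothelial genes were the only reference used. The test therefore does not decide whether a lower hepatocyte share is the whole cause. The same difference was 0.372 for stellate cell genes (exact permutation p = 0.2), 0.324 for macrophage genes (p = 0.257) and 0.182 for inflammatory genes (p = 0.286), so for these too a lower hepatocyte share stays open. More duct cells, and duct genes switched on in hepatocytes, stay open as untested biological explanations tied to the genotype.

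Other livers far from their group were control 3 for Lrtm2 at 0.295 CPM, control 1 for Pkhd1 at 10.02 CPM, knockout 1 for Orm3 at 0.0449 CPM (1 count, with 0 in the other knockouts) and knockout 2 for Sdcbp2 at 6.41 CPM. Knockout 2 was also far from its group for Serpina1d at 993.6 CPM, for the stellate cell list at 4.30 and for mitochondrially encoded messenger RNAs at 10.77 mean log2 CPM.

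No other split of the livers came near the real numbers of called genes. Of the 35 splits of the livers into 4 and 4, 1 gave as many higher genes as the real one (113, against 1 at the highest of the others), the real split itself, and 1 as many lower genes (161, against 1). That is the smallest share that 35 splits allow. The other splits mix the genotypes, which can widen the spread within their groups and lower their calls. The count therefore does not exclude chance by itself. For the number of gene lists the real split did not stand out, since 8 of the 35 splits gave at least its 16 lists and the highest other split gave 22. Splits that keep most livers of a genotype together, such as controls 1, 2 and 3 with knockout 3 (22 lists), retain part of the genotype contrast. The list count is therefore not a clean measure of chance either.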

How the results depend on the processing

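All alternatives were planned before the data were examined, except the removal of control 2 and knockout 4 together. The 274 called genes kept their direction in each alternative that tested them. Cebpa was called in every fit, with log2 fold changes from -5.54 (without knockout 2) to -5.28 (without knockout 1) when 1 liver was left out. The numbers of higher and lower genes were 388 and 462 with DESeq2, 23 and 24 with glmTreat against a fold change of 1.5, and 185 and 246 without control 2 and knockout 4 together. Lower genes numbered 70 on log2(TPM + 1) and 98 with the replicate block. Without 1 liver, the higher genes ranged from 46 to 167 and the lower from 61 to 205. Fewer samples are part of that construction, and the cause of other shifts was not tested. Orm1 kept its direction, with a log2 fold change of -8.80 (adjusted p = 0.0512) with library size alone, -8.87 (0.0682) without a filter, -8.65 (0.0746) with limma-voom and -8.45 (0.125) with the replicate block, all above 0.05. Without 1 liver it ran from -10.40 to -7.29, with adjusted p of 0.0259 to 0.146, and DESeq2 gave an adjusted p = 1.06e-11. Orm2 was not called in any of its alternatives (adjusted p 0.0963 to 0.452, no DESeq2 value). Orm3 had an adjusted p = 4.29e-05 with DESeq2 and 0.0157 without control 4, and 0.0766 to 0.186 in the other fits that tested it. Of 36 gene lists, 16 were called with the preset correlation, 0 with an estimated correlation and 4 with fry (hepatocyte secreted proteins, fetal genes, cholangiocytes and C/EBP factors), which tests another question. Further lists passed camera in some settings, among them C/EBP factors with library size alone (0.0344), without a filter (0.0282), without control 2 and knockout 4 together (0.0356) and with members of 1 list only (0.033). The C/EBP list holds Cebpa, the deleted gene, so its camera passes and its fry call are in part built in by the deletion. Nuclear oxidative phosphorylation passed with library size alone (0.00518) and mitochondrially encoded messenger RNAs without control 2 and knockout 4 together (0.00151). Cyp2e1, at a log2 fold change of -0.005, turned positive with library size alone (0.063), a 1 CPM filter (0.0026), log2(TPM + 1) (0.101) and in 5 leave-one-out fits, which ranged from -0.113 to 0.032. Among the 60 named genes called, 25 were called in all 8 leave-one-out fits. The replicate block called 176 genes and kept 143 of the 274. The numbers share no litter or day in the labels, and deviations of same-numbered livers correlated at 0.207, 0.009, -0.024 and -0.067, so not every liver matched best with its own number. Depth limited genes with few counts, such as Orm3, Spink1 and Cldn14.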

Other observations

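The genes in this paragraph were picked from the called genes after their values were seen. Together they form no fixed list and were not tested for enrichment, so they stand as single genes, though Serpina6 is also in the list of secreted proteins. Hsd11b1, which regenerates active glucocorticoid inside the cell, fell 8.19-fold, from 397.5 ± 36.8 to 48.5 ± 14.5 CPM (SD, n = 4, edgeR adjusted p = 0.000328), and was called in all 8 leave-one-out fits. Serpina6, the plasma glucocorticoid carrier, fell 1.88-fold (adjusted p = 0.0405), the steroid reductase gene Srd5a1 2.02-fold (0.0279), the oxysterol hydroxylase gene Cyp39a1 2.68-fold (0.0176) and the prolactin receptor gene Prlr 3.30-fold (0.0404). These 4 calls were lost in 2 to 7 leave-one-out fits, with adjusted p up to 0.119 for Prlr without knockout 2. Slc3a1, of the cystine transporter, fell 12.5-fold (0.014), and Got1, the cytosolic aspartate aminotransferase, 3.50-fold (0.0409). They lost the call in 2 and 7 leave-one-out fits, with adjusted p up to 0.0581 and 0.129 without knockout 2. Prlr and Srd5a1 overlap genes on their own strand, and Slc3a1 overlaps Prepl on the opposite strand.

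A sum over a gene family does not depend on how reads are divided within it. Summed over the family, the Mup genes were at 18920 ± 4860 CPM in controls and 8479 ± 3020 CPM in knockouts (SD, n = 4, exact permutation p = 0.0286, the smallest possible). Of 19 Mup genes tested, 7 fell, 17 had a negative and 2 a positive log2 fold change, and with library size alone 5 fell. Mup11 fell 6.50-fold (edgeR adjusted p = 0.0449) and Mup16 12.2-fold (0.0448). Both calls were lost with library size alone, at 0.0537 and 0.053, and in 7 of the 8 leave-one-out fits, with adjusted p up to 0.119 without knockout 1 and 0.118 without knockout 2. Over the 8 fits the log2 fold change of Mup16 ran from -4.58 to -3.37, against -3.61 with all livers. The Serpina1 genes summed to 20390 ± 3190 and 7907 ± 1010 CPM (SD, n = 4, exact permutation p = 0.0286), and all 5 tested fell under TMM, RLE and library size alone. The Gstm genes summed to 1014 ± 136 and 2083 ± 509 CPM (SD, n = 4, exact permutation p = 0.0286), with 4 of 8 tested, a pseudogene among them, called higher under these scalings, while the Gsta sum was 1605 ± 255 and 1755 ± 181 CPM (SD, n = 4, exact permutation p = 0.4).

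A shift toward the female pattern of liver expression is a candidate explanation for the fall of male-biased genes, tested after both lists had been seen. It would raise the female-biased list, whose camera adjusted p was 0.936 and whose median log2 fold change was -0.144, with 7 members positive and 8 negative. Since the members go both ways and few were tested, the list neither supports nor excludes such a shift.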
